A study of Mus musculus with 15 samples.

How the data were processed

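Total RNA of 15 samples of primary astrocytes from C57BL/6 mice was sequenced, 5 libraries in each of 3 groups. Libraries were made with a SMARTer mRNA kit from about 1.3 µg of RNA, per the labels' protocols. The labels put all libraries in batch 1. Nothing in the labels says whether the replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

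The deposited values are raw fragment counts per annotated row, made by the authors with featureCounts 2.0.1 in paired mode with strand option 2 and the GENCODE vM38 basic annotation, per the file headers. That annotation is on GRCm39. The submitters' processing notes name GRCm38 and mm10 as builds. The aligner is not given in the sources used here. The header's command lists 20 alignment files, and the table holds the columns of 15, all of which matched a sample through the library name in its description. Coordinates are printed as the table gives them, in GRCm39 numbers of the annotation. No coordinate was converted between builds.

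The table has 78275 rows, of which 26544 held a count in any library. Symbols were joined by gene ID from a table of GENCODE vM21 names, and 51486 IDs (65.8%) matched. The 37 rows of chromosome M and the 2052 rows of chromosome Y held 0 counts. Since 8 of 14 rows of abundant transcripts held 0 counts and the others at most 45 over all libraries, the symbols served only to test whether IDs name the genes behind the reads, and rows are described by ID and position. The planned fold change of Fabp5 and its permutation test could not be computed from a row with 0 counts in all libraries. Neighbouring rows may hold reads of one transcript, so a number of rows is not a number of genes.

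Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with its minimum count of 10, which left 7506, and library sizes were scaled by TMM. A single quasi-likelihood model with a mean for each of the 3 groups was fitted to all 15 libraries, and each comparison was tested two-sided with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM were computed from the counts and the TMM-scaled library sizes. List tests used camera of limma 3.58.1 with a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 5 rows tested.

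The groups, tests, lists, alternatives and naming rule were fixed before the data were examined. The rule names, for each comparison, 18 fixed genes and the 6 rows with the highest and the 6 with the lowest log2 fold changes among those that passed, had groups that do not overlap, reached a mean of 5 CPM in the higher group and carried a symbol that is not a predicted-gene name. It also names members of each list described. Because IDs do not name genes here, only the first 2 rows each way are printed, the rest are given as ranges, and no list is described by members. Fitted fold changes are given as ranges only over rows with at least 10 counts in the lower group, a limit set after the values were seen. Rows with 0 counts in a group are given as bounds against its highest floor. For printed rows that fell to fewer than 10 counts, also chosen after seeing the data, the ratio of summed counts per TMM-scaled library size is given with an exact conditional binomial interval, for counting error alone.

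Depth was 1176535 to 1359040 counts per library. On counts simulated from the real means, library sizes and dispersions with 200 rows changed, the test of LPS against Control recovered 76.0% of 2-fold and 99.0% of 4-fold changes over 7291 rows, with 7 false calls. For LPS+shFABP5 against LPS it recovered 75.0% and 94.0% over 7314 rows with 8 false calls, and for LPS+shFABP5 against Control 78.0% and 91.0% over 7288 rows with 10. These dispersions were estimated over all 15 libraries. At the highest, the chi-square statistic per row between replicates, described below, was 21.8 in Control, 2.7 in LPS and 3.4 in LPS+shFABP5. The simulated noise is therefore not that of LPS and LPS+shFABP5 alone, and recovery in their comparison may differ. Fragments without molecular identifiers are not independent molecules, so floors cover counting error only.

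Replicates were compared before averaging. The chi-square statistic per row between 2 libraries of a group, over rows with at least 20 counts in the pair, was 1.66 at the lowest and 21.8 at the highest, where counting noise alone gives 1, so no pair looked like repeat deposits of one library. The alternatives tried were DESeq2-type size factors, library size alone, no filter beyond 1 count, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom, the 2 compared groups alone, the replicate number as a block, leaving out each library in turn, a fold change of at least 2, and for lists an estimated correlation and fry. An alternative with 1 row per 100 kb was added after seeing the data.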

Results

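RNA from primary mouse astrocytes was counted in 15 libraries that fall into 3 groups of 5. The cells came from the cerebral cortex of pups at postnatal day 1 to 2. Control cells received no treatment. LPS cells received lipopolysaccharide, a bacterial cell wall component that activates innate immune signalling, at 1 µg/mL for 24 hours. LPS+shFABP5 cells received the same LPS together with plasmids that express a short hairpin RNA against Fabp5, a fatty acid binding protein, for 5 days. The labels name no group with a hairpin of another target, so the comparison of LPS+shFABP5 with LPS holds the plasmid treatment and the silencing together. The total count was 1268338 ± 56389 (SD, n = 5) in Control, 1270851 ± 75259 in LPS and 1269015 ± 36425 in LPS+shFABP5, and ranged from 1176535 to 1359040 per library. A count of 0 in a library allows up to 3 counts, for counting error alone. That floor is 1.96 to 2.67 when scaled to library size (CPM), with the TMM-scaled sizes used for every CPM given here.

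The hairpin's target could not be checked. The row with the ID of Fabp5 held 0 counts in each of the 15 libraries, so no fold change is given. The same held for transcripts that any cell makes in quantity. The rows of Actb, Gapdh, Rplp0, Ubb, Tmsb4x and Malat1 held 0 counts in all libraries, and those of B2m and Eef1a1 held 1 count each over the 15 libraries. These genes were picked after their values were seen. For a list fixed before the data were examined, the cytosolic ribosomal proteins, 6 of 47 rows (12.8%) reached 150 counts over all libraries and 27 held none. Among all 51486 rows with a symbol, 10.6% reached 150 counts and 64.0% held none. The rows of ribosomal protein genes, among the most transcribed of any cell, were thus filled about as often as any row. Among the 14 rows of the fatty acid binding protein list, the counts of all libraries added up to 34. Of the 18 genes chosen beforehand for this design, 8 had rows with 0 counts. The rows of Tnf, an inflammatory cytokine, and Hmox1, a heme-degrading enzyme, were the 2 that reached 150 counts, with 285 and 361 over all libraries. Neither total is read here as a level of that gene. Row IDs are therefore used below as labels of positions and not as names of genes, and no pathway or cell type is described.

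The groups differed in the counted positions. Over the 7506 rows tested, the first principal component of log2 CPM took 58.9% of the variance and separated Control from both LPS-treated groups. The median correlation of log2 CPM across rows, which are not independent replicates, was 0.856 between Control and LPS libraries and 0.964 between LPS and LPS+shFABP5 libraries. Within groups its median was 0.970 in Control, 0.972 in LPS and 0.970 in LPS+shFABP5. Control replicate 2 stood apart, with a mean correlation of 0.901 to the other Control libraries.

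**Figure D1:**
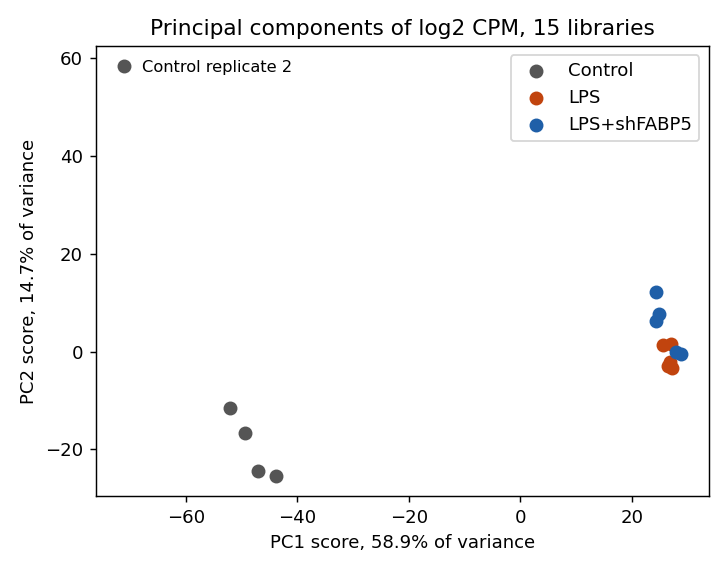
Scores of the 15 libraries on the first 2 principal components of log2 CPM over 7506 rows, coloured by group. Control lies to the left of both LPS-treated groups on PC1, which holds 58.9% of the variance, and Control replicate 2 lies apart on PC2, which holds 14.7%.

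LPS against Control asks what the treatment changed in astrocytes. Of 7506 rows, 2649 (35.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1309 higher and 1340 lower with LPS. With a fold change of at least 2 also required, 702 were higher and 489 lower. Of the 6 rows of the naming rule that rose most, 4 lay on chromosome 11 between 85723377 and 87481365. In 3 of the 6 every Control library held 0 counts, and they were at least 4.04-fold to at least 23-fold higher. The row ENSMUSG00000020486, annotated on chromosome 11 from 87457628 to 87481365, rose from 70.4 ± 78.0 CPM (SD, n = 5) in Control to 26800 ± 1400 in LPS, a log2 fold change of 8.56 (SE 0.49, edgeR adjusted p = 2.75e-12) that was 9.52 without Control replicate 5 and 9.22 with limma-voom. The row ENSMUSG00000055725, on chromosome 5 from 97230188 to 97259455, had 0 counts in every Control library and 61.5 ± 11 CPM (SD, n = 5) in LPS, at least 23-fold higher against the highest Control floor of 3 counts per library, 2.67 CPM (edgeR adjusted p = 9.6e-13). Of the 6 that fell most, the 3 with at least 10 counts in LPS had log2 fold changes of -3.98 to -3.73. The row ENSMUSG00000022229, on chromosome 14 from 56602525 to 56626007, fell from 27.6 ± 8.24 CPM to 0.306 ± 0.684 (SD, n = 5, edgeR adjusted p = 1.39e-08). It held 186 counts in Control and 2 in LPS, 81.8-fold lower (exact 95% interval 22.3 to 680, counting error alone). Both counts were in LPS replicate 4, and without that library it was at least 10.4-fold lower against the LPS floor. The row ENSMUSG00000029640, on chromosome 5 from 146671619 to 146731816, fell from 30.3 ± 8.97 CPM to 0.947 ± 1.25 (SD, n = 5, edgeR adjusted p = 5.37e-08). It held 204 and 6 counts, 29.9-fold lower (13.5 to 82.4), and 70.4-fold lower (19.2 to 585) without LPS replicate 4, which held 4 of the 6. In 1969 rows (26.2%) the 5 LPS libraries did not overlap the 5 Control libraries, where chance gives 0.794%. The balance of directions depended on the scaling: with library size alone, which moved the median log2 fold change of all rows from -0.02 to -0.21, 968 rows were higher and 2225 lower.

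LPS+shFABP5 against LPS asks what the hairpin plasmids changed under LPS. Here 136 of 7506 rows (1.81%) passed, 60 higher and 76 lower, and 31 of them by at least 2-fold. The rows of the naming rule had log2 fold changes of 1.17 to 2.71 for the 6 highest and of -1.94 to -1.14 for the 6 lowest. The row ENSMUSG00000030772, on chromosome 7 from 111715224 to 111758264, rose from 4.50 ± 1.58 CPM in LPS to 29.8 ± 5.28 in LPS+shFABP5 (SD, n = 5), a log2 fold change of 2.71 (SE 0.28, edgeR adjusted p = 7.73e-06). The row ENSMUSG00000019893, on chromosome 10 from 51922022 to 52071340, rose from 6.50 ± 4.10 to 28.2 ± 7.12 CPM (SD, n = 5, edgeR adjusted p = 0.00242). The row ENSMUSG00000056724, on chromosome 9 from 110453857 to 110483229, fell from 10.1 ± 2.87 to 2.57 ± 1.06 CPM (SD, n = 5, edgeR adjusted p = 0.0135), and missed the threshold without LPS replicate 5 (edgeR adjusted p = 0.0566) and without LPS+shFABP5 replicate 1 (0.0511). The row ENSMUSG00000030838, on chromosome 7 from 45844774 to 45887927, fell from 14.2 ± 1.61 to 5.29 ± 2.06 CPM (SD, n = 5, edgeR adjusted p = 0.0288). That call was not firm: with both other filters its edgeR adjusted p was 0.0884 and 0.056, with the replicate block 0.0631, and it was 0.0573 to 0.105 without LPS replicate 1, 3, 4 or 5 or without LPS+shFABP5 replicate 1, 3, 4 or 5, with a log2 fold change of -1.45 to -1.28. The groups did not overlap in 432 rows (5.76%). The count depended on the libraries used. It was 441 without Control replicate 2, a library of neither group compared, and 462 with the 2 compared groups alone. Leaving out any 1 library of the 2 compared groups lowered it, to between 79 without LPS replicate 5 and 106 without LPS replicate 3. It was 90 without LPS replicate 2, 82 without LPS+shFABP5 replicate 2, 88 without LPS+shFABP5 replicate 3 and 90 without LPS+shFABP5 replicate 4. With library size alone 47 rows were higher and 96 lower.

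**Figure D2:**
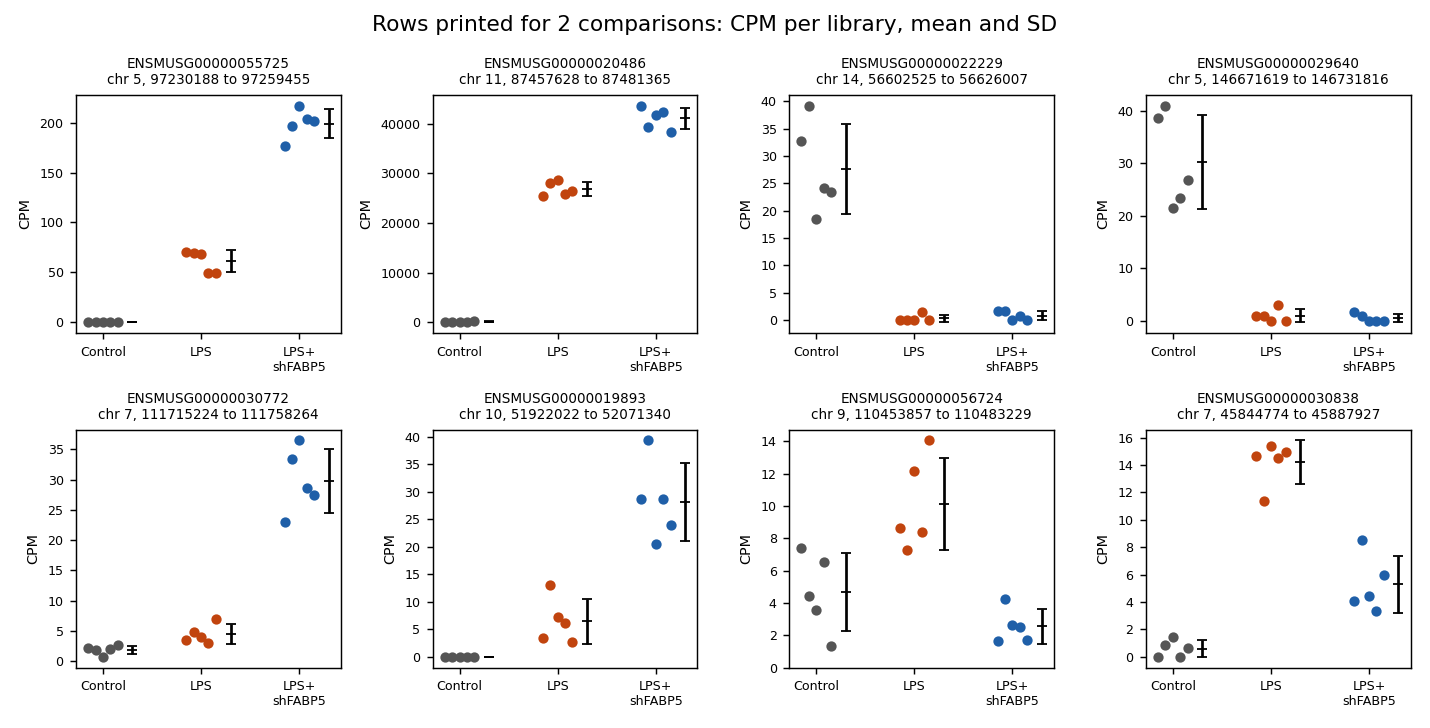
CPM per library in the 8 rows printed for the first 2 comparisons, each on a linear axis, with 5 points per group and the mean and SD as a bar at the right of the points. The row ENSMUSG00000020486 goes from 70.4 CPM in Control to 26800 in LPS and 41100 in LPS+shFABP5.

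LPS+shFABP5 against Control asks what remained different from untreated cells. Of 7506 rows, 2492 (33.2%) passed, 1248 higher and 1244 lower. Of the highest 6 rows of the naming rule, 3 held 0 counts in every Control library and were at least 6.02-fold to at least 74.4-fold higher. Of the lowest 6, the 2 with at least 10 counts in LPS+shFABP5 had log2 fold changes of -4.81 and -4.18. The 2 highest and the 2 lowest were the rows already given for LPS against Control. ENSMUSG00000020486 held 41100 ± 2190 CPM in LPS+shFABP5 (SD, n = 5), a log2 fold change of 9.17 that was 10.14 without Control replicate 5 and 9.83 with limma-voom. ENSMUSG00000055725 held 199 ± 14.5 CPM (SD, n = 5), at least 74.4-fold above the highest Control floor. ENSMUSG00000022229 and ENSMUSG00000029640 stood at 0.838 ± 0.837 and 0.499 ± 0.736 CPM (SD, n = 5). In counts they were 31.6-fold lower (exact 95% interval 13.3 to 98.6) and 57.8-fold lower (19.5 to 283), the second on 3 counts in LPS+shFABP5, of which 2 were in replicate 1, and 137-fold lower (24.4 to 5450) without that library. With library size alone 870 rows were higher and 2439 lower.

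Whether the hairpin plasmids moved rows back toward Control was counted over both comparisons. Of the rows that passed in both, 68 had opposite signs and 45 had equal signs. Of the 68, 53 were raised by LPS and lower with the hairpin, and 15 were the reverse. In 20 simulations of unchanged groups that shared the LPS libraries, no row passed in both. At most 1 row passed for LPS against Control there and at most 3 for LPS+shFABP5 against LPS, so that 0 is no baseline for 68 against 45. Independent lists of these sizes would share 24.0 rows with opposite and 24.0 with equal signs. With the LPS libraries split, 3 for one comparison and 2 for the other, 14 to 33 rows had opposite signs over the 20 ways of doing so, with a mean of 24.2, and 16.8 on average had equal signs, where independent lists of the sizes in those splits would share 6.50 and 6.37 on average. Without Control replicate 2 there were 193 rows of opposite sign, and 179 with the 2 compared groups alone. More rows passed for LPS+shFABP5 against LPS in these settings, 441 and 462 in place of 136. Rows of equal sign are not given for them, so 193 and 179 do not show a stronger move back. Leaving out any 1 LPS or LPS+shFABP5 library lowered the number, to between 39 without LPS replicate 5 and 50 without LPS replicate 3. There were 45 without LPS replicate 1, 45 without LPS replicate 2, 43 without LPS+shFABP5 replicate 2, 44 without LPS+shFABP5 replicate 3 and 45 without LPS+shFABP5 replicate 4. The covariance over rows of the 2 sets of log2 fold changes was -0.0422 over the 7506 rows tested, and depended on the filter: it was -0.160 over the 12090 rows with at least 1 CPM in 5 libraries and -0.610 over the 26544 rows with any count. The simulated and split values that follow are for the 7506 rows, and the jackknife, which leaves out each library, filtered the rows again each time. Simulations of unchanged groups that shared the LPS libraries gave -0.0306 ± 0.00126 (SD over 20 simulations). They drew the noise from dispersions estimated over all 15 libraries. The chi-square statistic per row between replicates reached 21.8 in Control, in a pair with replicate 2, and at most 2.72 in LPS. The simulated value can therefore overstate the part that the shared LPS libraries give. The observed minus the simulated covariance was -0.0116, and the jackknife standard error of the covariance was 0.0179. That error treats all 15 libraries as 1 sample and not as 3 groups, so it also holds shifts between groups. These values therefore do not decide whether the covariance goes beyond the shared libraries. With the LPS libraries split, so that none was shared, the covariance was -0.0230 on average. It ran from -0.0340 to -0.0154 over the 20 ways, which reuse the same libraries and are not independent.

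**Figure D3:**
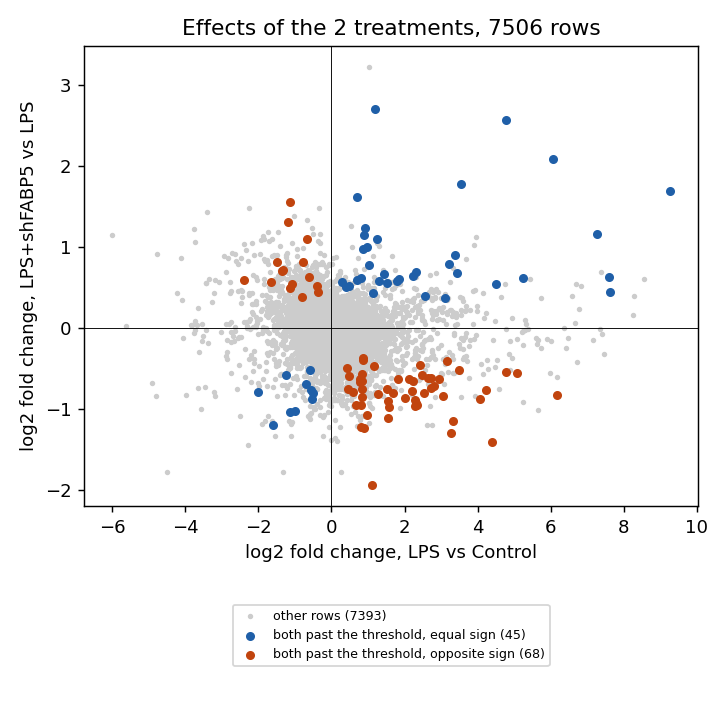
Log2 fold change of LPS+shFABP5 vs LPS against that of LPS vs Control for 7506 rows. Rows past the threshold in both comparisons are coloured, 68 with opposite and 45 with equal sign.

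The planned test of 37 gene lists was run although the IDs do not name genes, and its outcome says nothing of those genes. At least 5 rows were tested in 16 lists. With limma's camera, 0 of the 16 passed in each of the 3 comparisons, with 1 list at an unadjusted p under 0.05 for LPS against Control and 0 for both others. With an estimated correlation 0 passed as well. With fry, which does not compare a list with other rows, 10 lists passed for LPS against Control, 0 for LPS+shFABP5 against LPS and 11 for LPS+shFABP5 against Control.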

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

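The tests of Control replicate 2 on depth, on its highest rows and on a swap were chosen after the result was seen, and the one on row length before. In groups of 5, a sample was picked out when its gap to the nearest of the others took more than 0.71 of the group's range. This held in 5 of 36 groups of values, where chance gives about 1 in 20 for continuous values. That rate does not hold near 0 counts. ENSMUSG00000022229 in LPS took the whole range, a ratio of 1.0, on 2 counts in 1 library. The 5 of 36 can therefore overstate how unusual these libraries are.

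Control replicate 2 had a mean correlation of 0.9009 with the other Control libraries, whose own means lay between 0.951 and 0.958. It held counts in 12391 rows, against 14003 to 14874 in the other 4, and 1790 of 7506 rows were at least 2-fold lower and 98 at least 2-fold higher than their mean on the scale of log2(CPM + 2), CPM here without TMM scaling. A lower number of counted fragments is argued against by its total, 0.955 times the mean of the other 4. Numbers of sequenced reads were not examined, so a lower depth of sequencing is not excluded. A few rows taking most of the counts are argued against by its 10 highest rows, whose share was 1.10 times that of the others. A swap with another group is argued against by its correlations on that scale, at most 0.825 with a library of another group and at least 0.890 with a Control library. On the TMM-scaled log2 CPM behind 0.9009 they were at most 0.819 and at least 0.887. Its deviation on log2(CPM + 2) had a Spearman rho of -0.00912 with row length. That length is of the annotated row and not of the transcript behind the reads. The test therefore cannot decide on a bias by transcript length. A difference of the culture itself is only 1 of the explanations that stay open and were not tested.

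The row ENSMUSG00000020486 reached 205.15 CPM in Control replicate 5, above the other Control libraries. In LPS replicate 4, ENSMUSG00000022229 stood at 1.5306 CPM where the other LPS libraries held 0, and ENSMUSG00000029640 at 3.0611 CPM. In LPS replicate 2, ENSMUSG00000030838 stood at 11.371 CPM, below the other LPS libraries.

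How often other groupings of the libraries gave as much was examined with 100 of the 126 splits of each pair of groups, the real one included. For LPS against Control 1 split, the real one, reached 2649 rows, and the highest other gave 110. For LPS+shFABP5 against LPS 1 split reached 136 and the highest other gave 0. For LPS+shFABP5 against Control 1 split reached 2492 and the highest other gave 271. A random labelling of these libraries is argued against for these 3 counts. Splits that mix the groups add the group difference to the spread, which lowers their calls. The libraries may be technical replicates, so chance differences between cultures are not excluded. For rows of opposite sign, 1 split of LPS+shFABP5 and LPS, the real one, reached 68, but the other 99 called no row and so fixed their count at 0, and this test decides nothing. Among splits of LPS and Control, which put Control libraries into the LPS group, 1 other gave 89, and splits of LPS+shFABP5 and Control gave at most 13. For the covariance of -0.0422, 7 of the 100 splits of LPS+shFABP5 and LPS were as low, the lowest other at -0.0513, so chance is not excluded. Splits of LPS and Control ran from -0.354 to 0.0541 and those of LPS+shFABP5 and Control from -0.236 to -0.178. For the gene lists, with 0 passing in the real split, all 100 splits reached that in each comparison, and the highest other gave 1.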

How the results depend on the processing

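The 1 row per 100 kb fit was chosen after seeing the data. No value could be given for Fabp5 under any setting. Counts of changed rows stayed within 1.5 times of 2649, 136 and 2492 under the other size factors, library size alone, both other filters, DESeq2, limma-voom and the replicate block. The 1 CPM filter, planned as stricter, kept 12090 rows and was the looser one at this depth. The 2 compared groups alone gave 462 for LPS+shFABP5 against LPS and 179 of opposite sign. A fold of at least 2 gave 1191, 31 and 1144. With 1 row per 100 kb, LPS against Control gave 1457 and LPS+shFABP5 against Control 1402 of 3623 rows. Without single libraries the counts ran from 2404 to 3019, 79 to 441 and 2263 to 2991, rows of opposite sign from 39 to 193, and the covariance from -0.0542 to -0.0381. The covariance was -0.610 with no filter and -0.160 with the 1 CPM filter. The fold limit can only remove rows, and the fit with 1 row per 100 kb tested fewer rows. Control libraries can move the LPS+shFABP5 against LPS count only through the filter, the scaling and the shared estimate of spread. Which of these did so was not tested, nor was the cause of the other moves. Lists that passed were 2 for LPS against Control with no filter, and with fry 10 and 11 against Control. Without single libraries 0 to 0 lists passed. Of 847 values of named rows, 822 kept direction and threshold, 25 lost the threshold and 0 reversed. A further 17 could not be had: 2 of ENSMUSG00000020486 against Control, where DESeq2 gave no adjusted p, 2 in rows not tested with the 2 compared groups alone, and 13 in rows left out with 1 row per 100 kb.

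With the replicate number as a block, 2576, 107 and 2416 rows passed, 53 had opposite signs, the covariance was -0.0432 and 0 lists passed. The numbers did not pair the samples: same-numbered libraries of 2 groups had deviations correlated between -0.196 and 0.172, over 0.1 in 2 of 15 pairs, and 6 of 15 correlated best with their own number. Small changes were recovered only in part: 2-fold changes were recovered in 75.0% to 78.0% of simulated rows drawn from all rows tested. The simulated noise came from dispersions over all 15 libraries, so recovery for LPS+shFABP5 against LPS may differ. Whether depth or the spread between libraries limits recovery was not tested.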

Other observations

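The test of a fixed move of rows and the test of strand were chosen before their results were seen. The neighbour, GRCm38 and stretch tests were chosen after.

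The rows of ribosomal protein genes were filled about as often as any row, 12.8% against 10.6% at 150 counts, and 5 explanations were tested. IDs out of order with their counts are argued against by position: the log ratio of LPS to Control in rows within 5 kb of each other correlated at a Spearman rho of 0.583 over 930 pairs, against at most 0.124 in 1000 shuffles, and fell to 0.068 at 50 to 200 kb on the same strand. A fixed move of all rows is argued against, since no move of up to 2000 places put more than 25.5% of ribosomal protein rows at 150 counts. Reads on GRCm38 numbers, the build in the submitters' notes, are argued against as the whole cause only if reads were counted on the strand of their transcripts. Of 17 rows whose numbers overlap a GRCm38 ribosomal protein exon on the same strand, 4 (23.5%, exact 95% interval 6.81 to 49.9%) reached 150 counts. The upper limit lies just under the 50% bound, and overlaps on the opposite strand were not tested. Counting on the opposite strand stays open, since 46.0% of the 200 fullest rows (exact 95% interval 38.9 to 53.2%) overlap an opposite-strand exon, and the interval spans the 50% bound. The share among all rows was not taken, so the 46.0% has no baseline and this test cannot decide.

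A hypothesis is that the reads lie on the coordinates of another assembly that may run as a stretched copy of the annotation. This was the last of 4 forms of search tried. Of the earlier ones, 2 were void because exons matched themselves and 1 found no shift, and the thresholds, gene lists and tolerance of this form were picked after raised rows had been looked at. A single offset and stretch for all chromosomes put 38 of 98 LPS-raised positions within 0.4 Mb of 219 genes of 8 inflammation lists, at -4.6 Mb and 10%, against at most 23 in 100 random sets of positions and 20 with an offset alone. Fitted on odd chromosomes (-4.5 Mb and 10%) and read on even ones, 9 of 35 positions lay near such genes, against 2.61 on average in 999 random sets. Fitted on even chromosomes (-4.2 Mb and 9%) and read on odd ones, 16 of 63 did, against 5.86. The permutation p was 0.001 for each, the smallest these sets can give. The fits thus took different values, and a map common to all chromosomes is not shown. With positions merged within 1 Mb, because raised rows cluster, the fits gave 7 of 33 and 12 of 52, and the larger permutation p was 0.004. The split into chromosomes is no independent evidence, since the whole table had been seen. Most raised positions lay near no listed gene, the assembly was not identified, and no gene was named from this map.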
